A study of Homo sapiens with 6 samples.

How the data were processed

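RNA from MSTO-211H cells treated with 20 µM CBP or with 0.1% DMSO for 24 h was hybridised to Clariom S Human arrays, 1 biotin-labelled sample per array. The labels give 3 biological replicates per group, named here CTRL 1 to CTRL 3 and CBP 1 to CBP 3. The labels prescribe 100 ng of RNA per labelling; other steps of the array work were not used here.

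The deposited values are log2 probe set summaries, 1 per probe set and array. The submitters' processing notes name RMA and the Transcriptome Analysis Console, with versions not given in the sources used here. RMA corrects background, normalises the arrays to each other and summarises the probes of a set. Such values have no true zero, and differences between dim probe sets are compressed, so folds of dim genes are understated. The medians of the arrays lay between 6.74 and 6.80, and the values between 1.92 and 18.3, so they were not normalised again.

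The authors' deposited table gives, per the file headers, a signed fold score (a fall is written as minus the ratio) and a p-value for 595 probe sets, with annotation release na36 on hg38. Its header calls the treated group C3 and not CBP. Its folds matched the CBP and CTRL arrays in the value table: the difference of Tukey biweight group means (tuning constant 5) equalled the log2 of the fold to within 0.0036. The table states no test; 594 of its 595 p-values equalled those of limma to the rounding of their last printed digit (within 0.51 of a unit).

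The 24351 rows held 2903 control rows, which were left out of the tests: 612 negative controls, 2197 positive controls, 63 ERCC rows and 31 Affymetrix spike-in rows. The 21448 others were tested, among them 555 that the array design marks as unmapped. A linear model with 2 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes without trend or robust estimation), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The moderated test had 9.29 degrees of freedom. All tests were two-sided except the hypergeometric test. Exact permutation tests of 3 arrays against 3 cannot go below p = 0.1.

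A probe set was taken as not above background in a group when all 3 arrays lay under the 95th percentile of that array's negative controls, which was 7.67 to 8.01. A fold against such a group is given as at least N-fold: the brighter group's mean against the mean of, per array, the higher of that percentile and the probe set's own value. No fold is given where this is under 1 or both groups were dim. By this measure 53.1% of the tested probe sets were dim in both groups.

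Gene symbols were taken from the deposited table, since no other annotation of the probe sets was used here. Of its 595 probe sets, 569 had 1 symbol and 26 several. Those with several, and 38 with 1 symbol that describe circular RNAs or AceView transcripts, named no gene, which left 526 genes with 1 probe set each, the one with the highest mean. A RefSeq gene table of GRCh38.p14 held 524 of these, updated 25 symbols and gave the gene coordinates. Gene names in the text are those of the deposited table, such as AARS and CARS, which are now AARS1 and CARS1. Probe sets outside the table remain unnamed here.

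Before the data were examined, 43 gene lists and the rule for named genes were fixed. The rule took up to 12 genes in each direction with the largest change among probe sets with an adjusted p under 0.05, non-overlapping groups, 1 symbol and a mean in the brighter group at or above the median. It gave 6 genes that rose and 12 that fell. From lists with a changed member it took up to 4 changed members, and from other lists up to 2. Further list members in the text were chosen after their values were seen. The value of 1 list member is not reported here. The planned test of each list against all other genes (camera, preset correlation 0.01) could not be run as planned, because the names cover selected probe sets alone. It was run against the other named genes of the table for the 6 lists with at least 5 members there. A hypergeometric test of list members among the table's entries was added, with all 21448 probe sets as background, and again with the 10053 above background in at least 1 group. Both drew all table entries in the background, while members could be counted only among the 526 named genes. The chance counts are thus slightly high. Fisher's exact test compared the directions of a list with those of the other named genes, and 4 of the 6 lists passed after adjustment: ATF4 (0.00153), G1 and S phase (0.00053), NF-kB (0.0224) and epithelial to mesenchymal transition (0.00546). This test takes genes as independent, and the camera adjusted p of these lists with an estimated correlation was 0.0888, 0.163, 0.116 and 0.0888. For counts adjusted over the list alone, members without a name were given a p of 1.

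The fit was tested on simulated data, 20 sets of 21448 probe sets with 200 changed. It recovered 19.5% of 2-fold, 77.0% of 4-fold and 93.1% of 8-fold changes, with 4.11% of its calls false. The simulated noise was independent between probe sets, so these shares need not hold for arrays whose probe sets vary together. The Benjamini-Hochberg cut-off is also stricter where fewer probe sets are called. The real comparison called 21, so it may recover changes of these sizes less often than the simulated sets with 200 changed. Alternatives were the replicate number as a block, median centring, quantile normalisation, leaving out dim probe sets, an intensity trend with robust estimation, array weights, leaving out each array, other thresholds, an unmoderated test and other forms of camera. A covariate from the poly-A spike-ins and the Tukey rule of the deposited table were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.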

Results

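Gene expression was measured in MSTO-211H, an established human malignant mesothelioma cell line, with Clariom S Human arrays, 1-colour arrays that read 1 biotin-labelled sample each. The 6 arrays fell into 2 groups of 3 biological replicates. The CBP group received 20 µM of a treatment labelled CBP for 24 h, and the CTRL group received the vehicle, 0.1% DMSO. The labels used here do not spell out CBP, and the comparison asked which transcripts differed between treated and vehicle cells. The series title concerns curcumin and sensitivity to cisplatin in mesothelioma. All values are log2 probe set values as deposited, and the number of arrays limits the precision. The labels call the replicates biological without naming the cultures, so the p-values measure the spread between these 3 samples per group.

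After CBP, 6 probe sets rose and 15 fell of 21448 tested at an adjusted p under 0.05 (limma, Benjamini-Hochberg over all probe sets). The genes that rose included CXCL8, which encodes the neutrophil chemokine interleukin-8, and the cyclin E genes CCNE1 and CCNE2, which act at the entry into S phase. The genes that fell included the glycine transporter gene SLC6A9 and the stress response genes TRIB3 and DDIT3. All 21 had a fitted log2 change of at least 1 in size, which is no bound on the fold where a group lay below the negative controls, and in all 21 the 3 CBP arrays lay on one side of the 3 CTRL arrays. Over all probe sets, 18.2% had such non-overlapping values, where chance gives 10%. The count was 3 without CBP 1, 3 without CBP 2, 10 without CBP 3, 13 without CTRL 2, 18 without CTRL 1 and 29 without CTRL 3. The median SE of a change was 0.249 on the log2 scale, and 2595 probe sets had an unadjusted p under 0.05.

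CXCL8 lay below the level of the negative control probe sets in CTRL, at 5.63 ± 0.48 (SD, n = 3), and at 10.94 ± 0.67 in CBP. Against the negative control level it was at least 8.38-fold higher in CBP (adjusted p = 0.00235, limma). The gene lies on chromosome 4 from 73740569 to 73743716 (GRCh38). RGS4, a regulator of G protein signalling, rose from 10.71 ± 0.32 to 13.63 ± 0.59 (SD, n = 3), which is 7.54-fold (adjusted p = 0.02, limma). It lies on chromosome 1 from 163068871 to 163076802. ROMO1, which encodes a mitochondrial membrane protein, rose 3.51-fold (adjusted p = 0.0488). FLG, the filaggrin gene of the epidermis, was at least 1.38-fold higher in CBP (adjusted p = 0.0497, limma), with CTRL below the negative control level. On CBP 3 it read 7.15, also below that array's level of 7.67, so the bound holds for the group mean and not for each array. In the authors' deposited table the folds of CXCL8 and FLG were 48.61 and 29.99. Those are ratios of Tukey biweight means of the values themselves, so they cannot be set against the bounds given here.

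SLC6A9 fell from 11.68 ± 0.11 in CTRL to 8.21 ± 0.65 in CBP (SD, n = 3), a log2 change of -3.47 ± 0.31 (SE) with an adjusted p of 0.00701 (limma). It lies on chromosome 1 from 43996483 to 44031462 (GRCh38). PCK2, the mitochondrial phosphoenolpyruvate carboxykinase gene, was at least 1.59-fold lower (adjusted p = 0.00602), with CBP below the negative control level. It lies on chromosome 14 from 24094171 to 24104125. Among genes for surface and signalling proteins, BCAM, a laminin-binding adhesion protein of the basal cell surface, fell by 2.67 ± 0.36 (SE), and the collagen receptor gene DDR2 fell by 1.92 ± 0.27. LURAP1L fell by 2.67 ± 0.37. ADCYAP1, which encodes the neuropeptide PACAP, was at least 1.47-fold lower, and TCP11L2 at least 2.36-fold lower. The adjusted p of these 5 genes lay between 0.0306 and 0.0499. CXCL8 and PCK2 passed the test in all 13 alternative moderated fits, SLC6A9 and DDIT3 in 12 and CCNE2 in 11. RGS4 and TRIB3 passed in 10 of the 13, ASNS in 9, ADCYAP1 and AARS in 8 and ROMO1 in 7. FLG, CCNE1, LURAP1L, BCAM and DDR2 passed in 6 of the 13, TCP11L2 in 5 and CEBPG in 4. The unmoderated test, which is not among the 13, passed 0 probe sets, so each of these genes missed it. The other 3 of the 21 probe sets were a dim one for FA2H, an AceView transcript assigned to ZZZ3, and TC0300013831.hg.1, which carries 2 gene symbols; they fell outside the rule for named genes and are listed here after their values were seen.

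**Figure D1:**
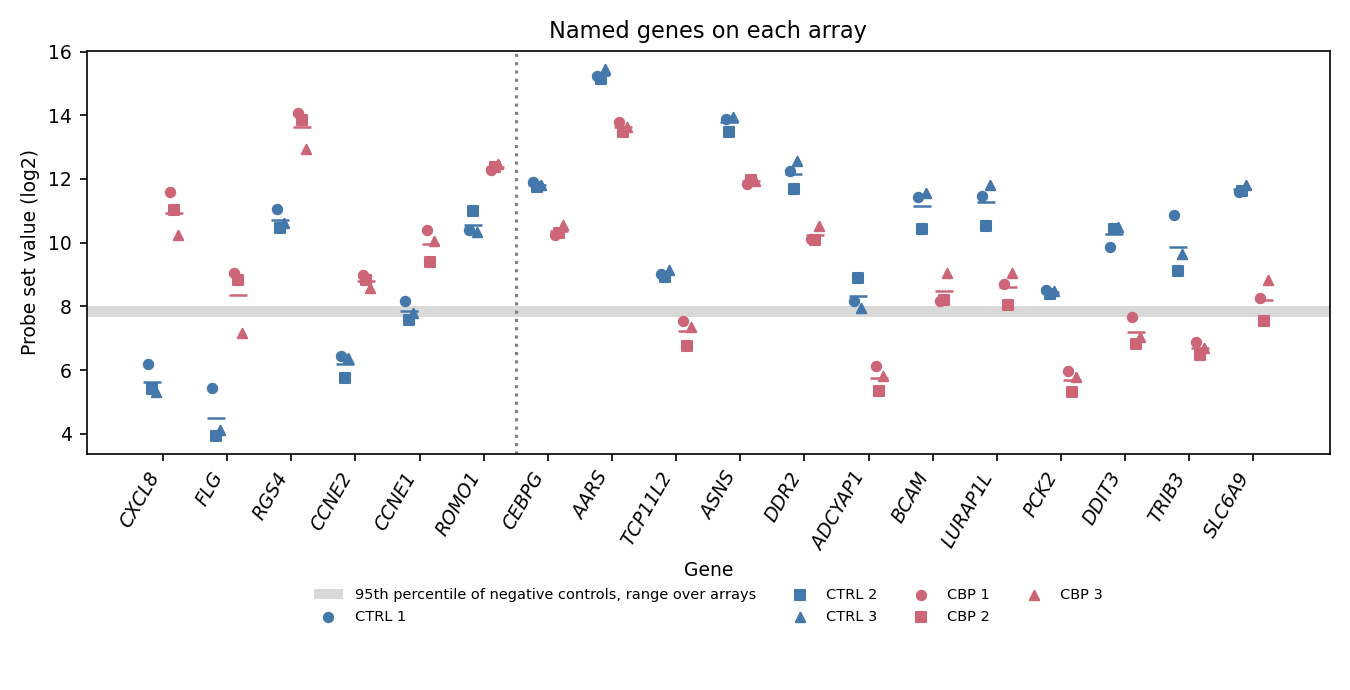
Log2 probe set values (y axis) of the 18 named genes (x axis) on each of the 6 arrays, with CTRL in blue, CBP in red, symbols for replicates and short lines for group means. The grey band spans the 95th percentile of the negative controls over the arrays, 7.67 to 8.01. The 6 genes left of the dotted line were higher on every CBP array, and the 12 to its right lower.

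The integrated stress response is a set of genes that the transcription factor ATF4 drives when amino acids run short or proteins misfold. Of the 36 genes of this list, 5 fell over all probe sets tested (TRIB3, DDIT3, ASNS, AARS and CEBPG), and adjusted over the list alone 18 were lower and 1 was higher. Of the 36, 17 were not in the table and have no value here, and with an estimated correlation the adjusted p of the list was 0.0888. DDIT3, which encodes the transcription factor CHOP, was at least 5.57-fold lower (adjusted p = 0.00701, limma), and TRIB3, a pseudokinase gene, at least 4.27-fold lower (adjusted p = 0.0346). ASNS, asparagine synthetase, fell by 1.85 ± 0.21 (SE, log2), from 13.77 ± 0.26 to 11.92 ± 0.06 (SD, n = 3). AARS, alanyl-tRNA synthetase, fell by 1.66 ± 0.21, and CEBPG, a partner of ATF4, fell by 1.45 ± 0.20. The serine synthesis genes PHGDH and PSAT1 had log2 changes of -2.41 ± 0.42 and -1.73 ± 0.27, and the cystine transporter gene SLC7A11 -1.71 ± 0.29. These 3 had adjusted p-values of 0.0774, 0.062 and 0.0765 over all probe sets and passed adjusted over the list alone. The 1 higher member, ALDH1L2, lay below the negative control level in both groups.

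Gene names came only from the authors' deposited table of 595 probe sets, which had been chosen on these samples, so the counts of list members are not independent evidence of direction. That table held 19 of the 36 ATF4 list genes, where 1.00 would be drawn by chance (hypergeometric adjusted p = 4.73e-19, which takes genes as independent). Of the table's 526 named genes, 298 were lower. Against the other named genes of the table the camera adjusted p of the ATF4 list was 0.000109 with the preset correlation, and 0.0888 with an estimated correlation. Among the markers of other cell types, the table held the macrophage marker CD68, at least 2.16-fold higher, and the stromal markers THY1 and PDGFRB, with log2 changes of 1.48 ± 0.30 and -1.73 ± 0.51 (SE). Over all probe sets these 3 missed the threshold, with adjusted p-values of 0.0731, 0.117 and 0.233.

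Of the 41 listed genes of the G1 to S transition and DNA replication, CCNE2 and CCNE1 rose over all probe sets, and 8 were higher adjusted over the list alone. Of the 41, 30 were not in the table and have no value here, and with an estimated correlation the adjusted p of the list was 0.163. CCNE2 was at least 1.90-fold higher (adjusted p = 0.00857, limma), with CTRL below the negative control level. CCNE1 rose by 2.11 ± 0.29 (SE, log2), from 7.84 ± 0.31 to 9.95 ± 0.50 (SD, n = 3, adjusted p = 0.0497, limma). On CTRL 2 and CTRL 3 it read 7.56 and 7.79, below the negative control levels of those arrays, 8.01 and 7.89. Its adjusted p was 0.0547 with the array medians centred and reached 0.249 without CBP 1. PCNA, the sliding clamp of the replication fork, had a log2 change of 1.61 ± 0.34 (adjusted p = 0.12), and CLSPN, a checkpoint protein of the fork, 1.70 ± 0.38 (adjusted p = 0.139). The table held 11 of the 41, all of them higher, where 1.14 would be drawn by chance (hypergeometric adjusted p = 2.17e-07). Against the other named genes the camera adjusted p was 0.000114 with the preset correlation. The table held 0 of the 41 genes of the G2 and M phase list, where 1.14 would be drawn by chance (exact hypergeometric lower-tail p = 0.315), and their levels were not analysed here.

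CTRL 3 stood apart in this group of genes. It had the lowest CTRL value for 9 of the 11 members, and the median of the members was 7.55 on CTRL 3, 8.39 on CTRL 1 and 9.22 on CTRL 2. On CBP 1, CBP 2 and CBP 3 this median was 10.23, 9.60 and 9.94. CBP 3 in turn had the lowest CBP value for 9 of the 11 members. RRM2, a ribonucleotide reductase subunit gene, read 8.75 on CTRL 3 and 11.34 and 12.12 on CTRL 1 and CTRL 2, against 12.19 to 12.79 in CBP. The median log2 change of the 11 members was 1.61 with all arrays, 1.57 with members below the negative controls at their bound, and 1.12 without CTRL 3. Adjusted over the list alone, 5 members passed without CBP 2. CTRL 3 also had the highest level of poly-A spike-in controls, at 8.24 against 6.58 and 6.86 on the other CTRL arrays and 7.08, 7.60 and 7.97 on the CBP arrays.

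**Figure D2:**
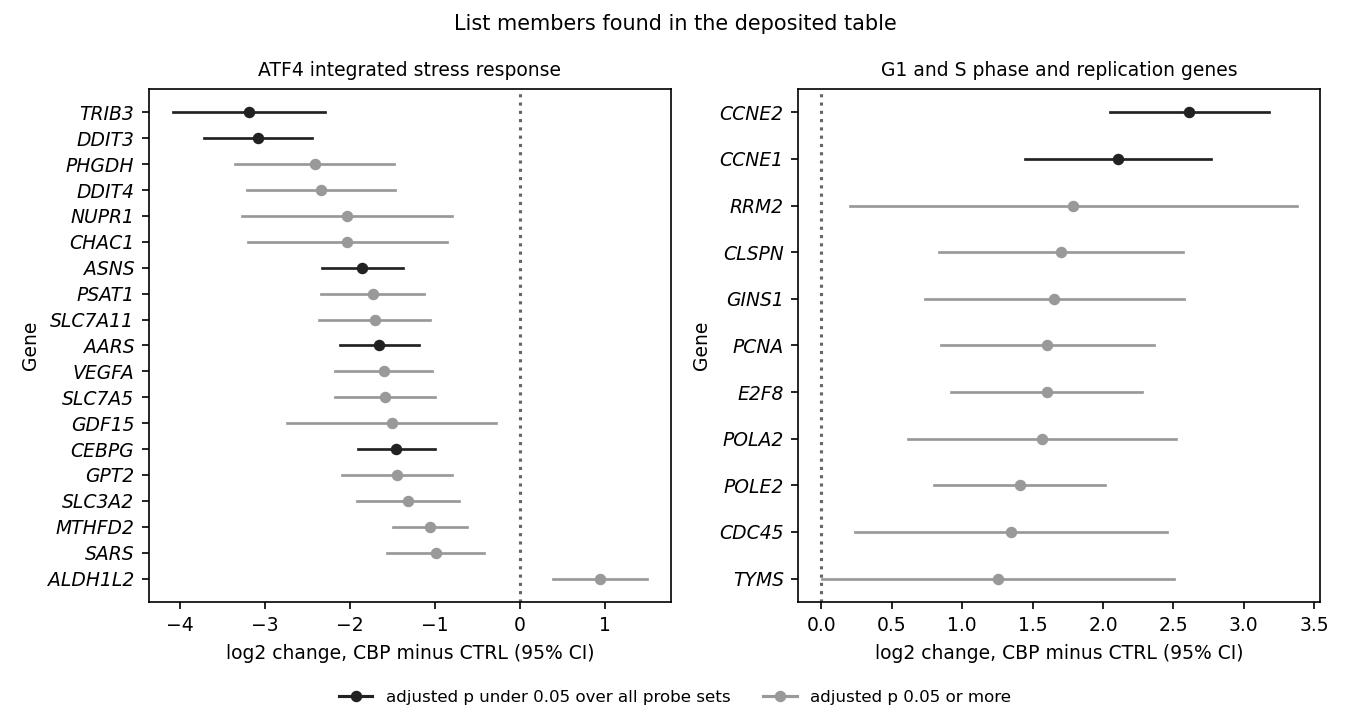
Log2 change (x axis, CBP minus CTRL) of the 19 ATF4 list members and the 11 G1 and S phase list members found in the deposited table (y axis), as points with 95% confidence intervals from limma (fitted values, not bounds, for members below the negative controls in a group). Black marks genes with an adjusted p under 0.05 over all probe sets, 5 on the left and 2 on the right; 18 of the 19 lie below 0 and all 11 above it.

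**Figure D3:**
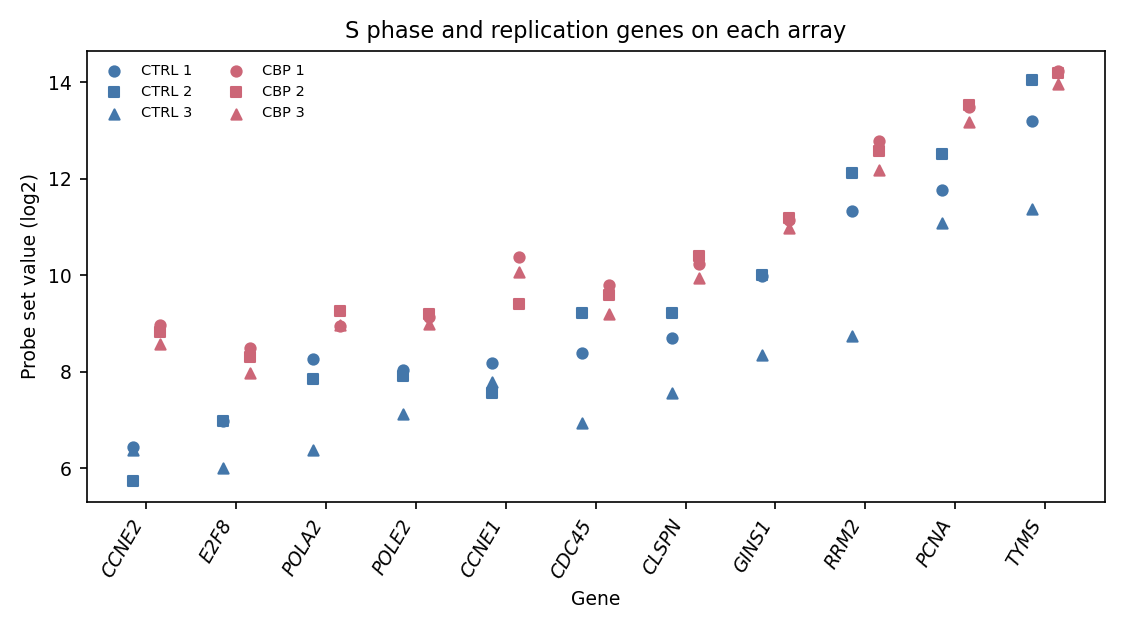
Log2 probe set values (y axis) of the 11 G1 and S phase list members (x axis) on each array, with CTRL in blue, CBP in red and symbols for replicates. CTRL 3, the blue triangles, has the lowest CTRL value for 9 of the 11 genes. CBP 3, the red triangles, has the lowest CBP value for 9 of the 11, while the CBP arrays lie close together.

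Inflammatory genes that NF-kB controls were the third group. Of 32 listed, CXCL8 rose over all probe sets, and 5 were higher adjusted over the list alone. The cytokine gene IL1B had a log2 change of 2.63 ± 0.59 (SE; adjusted p = 0.139), IL1A 1.57 ± 0.33 (adjusted p = 0.122), and TNFAIP3, a feedback inhibitor of NF-kB, 2.43 ± 0.44 (adjusted p = 0.088, limma). The fifth, BIRC3, lay below the negative control level in CTRL. The table held these 5, where 0.89 would be drawn by chance (hypergeometric adjusted p = 0.0125, and 0.108 among probe sets above the negative controls). The camera adjusted p was 0.000915, and 0.116 with an estimated correlation.

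The list of genes of the epithelial to mesenchymal transition had 7 of its 32 genes in the table, all higher, and 0 of them passed over all probe sets (limma). All 7 had an unadjusted p under 0.05, as every entry of the table does by its own rule. Adjusted over the list alone, 5 were higher. The collagen crosslinking enzyme gene LOX had a log2 change of 1.67 ± 0.35 (SE; adjusted p = 0.117), and TGFBI, a matrix protein gene, 1.75 ± 0.33 (adjusted p = 0.102). The hypergeometric adjusted p was 0.000323. The camera adjusted p was 0.00206, and 0.0888 with an estimated correlation. The list of secreted factors of senescent cells had 6 of 24 genes in the table, 5 higher and GDF15 lower. Of these CXCL8 passed over all probe sets, and 4 were higher adjusted over the list alone (hypergeometric adjusted p = 0.00042; camera adjusted p = 0.00686, and 0.163 with an estimated correlation). It shares genes with the lists above, CXCL8 and MMP1 among them.

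Of the 31 genes of the p53 target list the table held 4 higher and GDF15 lower, 3 of them higher adjusted over the list alone and 0 past the test over all probe sets (limma; all 5 had an unadjusted p under 0.05, by the table's own rule). Among the higher ones, TP53I3 lay below the negative control level in both groups. SESN1, a stress-induced sestrin, had a log2 change of 1.57 ± 0.24 (SE; adjusted p = 0.058), and the cell cycle inhibitor CDKN1A 1.17 ± 0.39 (adjusted p = 0.287). The hypergeometric adjusted p was 0.0125. The list did not stand apart from the other named genes (camera adjusted p = 0.082, and 0.163 with an estimated correlation).

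The clock, interferon and ferroptosis lists had 4 genes each in the table and passed the hypergeometric test, with 0 members past the test over all probe sets (limma; each had an unadjusted p under 0.05, by the table's own rule). The clock and FOXO target genes NR1D1, NR1D2, PER3 and KLF9 were all lower, 4 of 23 listed, and passed adjusted over the list alone (hypergeometric adjusted p = 0.0209). PER3 lay below the negative control level in both groups. NR1D2, the clock repressor REV-ERB beta, had a log2 change of -1.10 ± 0.22 (SE; adjusted p = 0.117). The interferon response genes IFI44, IFI6, IFIT3 and DDX58 were all higher, 4 of 30 listed, with 2 past the test adjusted over the list alone (hypergeometric adjusted p = 0.0433). IFI44 had a log2 change of 1.70 ± 0.31 (adjusted p = 0.0911). The ferroptosis list had 3 lower and 1 higher of 24 (hypergeometric adjusted p = 0.0216), and its lower members SLC7A11 and CHAC1 are also on the ATF4 list. These lists, the NF-kB list and the p53 list missed the threshold when the hypergeometric background was limited to probe sets above the negative controls, with adjusted p-values of 0.321, 0.223, 0.144, 0.108 and 0.223 in that order.

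For the lists that follow, higher and lower give the sign of the difference of group means, and for some genes the arrays of the groups overlapped. Lists with 3 genes in the table were the NRF2 targets, all lower and led by SLC7A11, and the unfolded protein response, with HERPUD1 (-1.73 ± 0.29, SE) and ERN1 lower and MANF higher. CDK inhibitors and G1 cyclins had 3 higher (CCND3, CDK2 and CDKN1A). So did homologous recombination and Fanconi genes (EXO1, RAD54L and FANCB). The YAP and TEAD targets AJUBA, RBMS3 and TEAD4 were lower, and growth factor signalling had HBEGF higher, PDGFRB lower and FGFR1 below the negative control level in both groups. Over all probe sets 0 members of these 6 lists passed (limma; each had an unadjusted p under 0.05, by the table's own rule). The hypergeometric adjusted p of these 6 lists lay between 0.0546 and 0.145, and adjusted over the list alone 2, 3, 2, 0, 2 and 1 of their members passed, in the order given.

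Lists with 2 table genes were immediate early genes (MYC and ZFP36 lower), autophagy (ATG4A higher, GABARAPL1 lower), glycolysis and hypoxia (NDRG1 and VEGFA lower, both past the test adjusted over the list alone), extracellular matrix (POSTN higher, LAMA3 lower), fibroblast markers (above) and housekeeping genes (POLR2A and TFRC higher). Of the mesothelial markers, ITLN1 read 9.57 ± 2.33 (SD) in CTRL and lay below the negative control level in CBP and on CTRL 2, with overlapping groups. MSLN had a log2 change of -1.22 ± 0.41 (SE), and the adjusted p-values were 0.259 and 0.295. Lists with 1 table gene were heat shock (HSPA4L higher), apoptosis promoters (CASP6 higher), apoptosis inhibitors (BIRC3 higher), platinum transport and glutathione (SLC47A1 lower), cholesterol synthesis (CYP51A1 lower), ribosome biogenesis (MYC lower), tubulins (TUBA4A higher) and myeloid markers (CD68). Of these genes, ATG4A, BIRC3, CD68, THY1 and PDGFRB also passed adjusted over the list alone. None of these 15 lists passed the hypergeometric test, and 0 of their members passed over all probe sets (limma; each had an unadjusted p under 0.05, by the table's own rule). The other 13 lists had none of their listed genes among the 526 named genes of the table. They were G2 and M phase genes, metallothioneins, nucleotide excision and mismatch repair, proteasome subunits, fatty acid synthesis, oxidative phosphorylation, ribosomal proteins, replication-dependent histones, aryl hydrocarbon receptor targets, and lymphoid, endothelial, lung epithelial and erythroid markers. The lists do not hold every gene of their kind: the table also named the histone gene HIST1H4L and the ribosomal protein gene RPS29, both unlisted and below the negative control level in both groups. Its entries for HIST1H4C, which is listed, and RPS3A, which is not, describe circular RNAs and named no gene, as did entries that join DGAT1 or LPIN1 of the fatty acid list with a microRNA.

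The authors' deposited table lists 595 probe sets, 243 with a positive and 352 with a negative fold, all at least 2 in size. All 21 probe sets past the adjusted p lie in it with the same direction. The 595 were exactly the probe sets with a limma p under 0.05 before adjustment and at least a 2-fold difference between Tukey biweight means of the groups. By arithmetic means, 424 of the 595 differed by at least 2-fold and 171 did not, and 109 probe sets outside the table did with an unadjusted p under 0.05. At an unadjusted p of 0.05 the adjusted p reached 0.413.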

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

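The spike-in covariate and the Tukey biweight rule were chosen after seeing the data; the other alternatives were set before the data were examined. The count of changed probe sets, 21 with 6 higher and 15 lower, moved with most choices, and so did the number shared with the deposited table. Median centring gave 12 (8 lower), with 12 at least 2-fold and 12 shared. An intensity trend with robust estimation gave 44 (15 higher, 29 lower), array weights 112 (46 and 66) and the spike-in covariate 180 (100 and 80, 139 shared), and each of these kept all 21. An adjusted p under 0.01 left 5 (2 and 3). An unadjusted p with 2-fold gave 533 (214 and 319, 424 shared), and the Tukey rule 595 (243 and 352; 424 at least 2-fold, 595 shared). The unmoderated test, with few degrees of freedom, gave 0 in each count, with 2220 at an unadjusted p under 0.05, against 2595 by limma. Leaving out 1 array, which leaves fewer samples, gave 3 to 29 changed, 1 to 11 higher, 2 to 20 lower, 3 to 29 at least 2-fold and 3 to 26 shared. Of the 21, 3 remained without CBP 1, 3 without CBP 2 and 9 without CTRL 1. S phase list members adjusted over the list alone ranged from 5 (without CBP 2) to 11, against 8. Of the 18 lower ATF4 list members, 17 or 18 remained in each of the 13 alternative moderated fits. These members had been selected as changed on the same 6 arrays, so most were likely to remain in advance. Their number is no independent evidence of a fall. The 5 lists past camera, ATF4 among them, fell to 0 with an estimated correlation. Apart from the causes named, the cause was not tested.

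Whether the replicate numbers pair the arrays was not settled. Same-numbered arrays had correlations of deviations of 0.139, -0.0565 and 0.133. The best partner had the same number for replicates 1 and 3, but not for replicate 2. Poly-A spike-in levels rose from replicate 1 to 3 in CTRL (6.58, 6.86 and 8.24) and in CBP (7.08, 7.60 and 7.97). The hybridization controls rose in the same order in both groups. A difference shared by same-numbered arrays therefore remains possible. A fit with the replicate block gave 29 changed probe sets, 10 of them higher and 17 shared with the 21. Of 1040 values of 80 single-gene results in 13 settings, 0 reversed direction, 82 lost the threshold and 57 gained it. These genes had been selected as changed on the same arrays, and some settings leave the log2 change as it was. A reversal was therefore hardly possible, and its absence is no evidence of direction. The alternative of 1 probe set per gene was not run, because names cover selected probe sets alone. Signal over background limits the folds of the 53.1% of probe sets that were dim in both groups.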

Other observations

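The tests of the splits for the counts of probe sets, of the G2 and M phase list, of the tRNA synthetases, with the spike-in covariate as an alternative, and of CTRL 3 as the source of its calls were chosen only after the result was seen. Genes outside the fixed lists had changes of similar size that missed the adjusted threshold, and they were picked after their values were seen. CYP24A1, the vitamin D 24-hydroxylase gene, had a log2 change of 3.00 ± 0.59 (SE; adjusted p = 0.11, limma), and its values were spread in CTRL (10.74 ± 1.47, SD, n = 3) and tight in CBP (13.74 ± 0.04). VEGFC, a growth factor of lymphatic vessels, was at least 3.53-fold higher (adjusted p = 0.0555). ITGA2, a collagen-binding integrin, had a change of 2.37 ± 0.37 (adjusted p = 0.062) and MICAL2, an actin oxidase gene, 2.32 ± 0.33 (adjusted p = 0.0512). CBS, which feeds homocysteine into cysteine synthesis, was at least 4.21-fold lower on one of its probe sets and at least 3.48-fold on the other (adjusted p = 0.109 and 0.117).

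The lower level of the ATF4 list genes was weighed against technical explanations. With 1 array left out the smallest median change of the 19 members was -1.56 (without CTRL 1), against -1.66 with all arrays. The median over all arrays was -1.60 with members below the negative controls at their bound. These members had been selected as changed on the same 6 arrays, and the 17 listed genes outside the table have no value. A median over such members could hardly vanish, so it cannot tell whether 1 array carried the fall of the list. With the poly-A spike-in level as a covariate the median was -1.68. This level differed little against its spread, with 7.23 ± 0.89 in CTRL and 7.55 ± 0.45 in CBP (SD, n = 3). The covariate could thus hardly move the median of selected members, and it cannot decide on unequal RNA input or labelling. Probe sets of the same brightness had a median change of -0.0228, so the deposited values held no general fall at that brightness. RMA had already normalised the arrays to each other, so a small median was likely in advance. A lower ATF4 output in CBP cells than in vehicle cells is a hypothesis beside these explanations. No test of it on independent samples was possible here.

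ATF4 also regulates further tRNA synthetase genes. Of 16 cytosolic synthetase genes not on the fixed list, 2 were named by the deposited table and both were lower: CARS with a log2 change of -2.06 ± 0.31 (SE) and YARS with -1.21 ± 0.24 (adjusted p = 0.0579 and 0.111, limma). An entry that joins MARS with a microRNA, with a fold of -2.13 in the authors' deposited table, named no gene and was not counted. The hypergeometric p was 0.0277, but this family was picked after its genes had been seen as lower in the same arrays, so the p decides nothing about a wider fall.

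The higher level of the G1 and S phase genes was weighed likewise. The smallest median change with 1 array left out was 1.12 (without CTRL 3), against 1.61 with all arrays, so CTRL 3 added to the median of these members. The 11 members had been selected as higher with CTRL 3 included, and the 30 listed genes outside the table have no value. Whether CTRL 3 alone makes the rise of the list can therefore not be told. The median was 1.85 with the spike-in covariate, which for members so selected cannot decide on labelling. Probe sets of the same brightness had a median change of -0.0659, so the deposited values, after RMA, held no general rise at that brightness. A larger share of all cycling cells would raise G2 and M phase genes too. Of the 41 listed, 0 were among the table's named genes, but the hypergeometric lower-tail p of 0.315 is too weak to tell. The list does not hold every gene of its kind. The table also had entries for the mitotic genes MASTL and CENPI, higher, and RCC2, lower, which were not counted for it. A gain of cells in late G1 or S phase, and cultures of unequal growth with CTRL 3 as the slowest, may both contribute and remain open. CBP 3 also had the lowest CBP value for 9 of the 11 members, and a difference shared by the replicate 3 arrays was not tested.

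The count of changed probe sets rose from 21 to 180 when the spike-in level was a covariate, and 41 of the 180 lay outside the deposited table. The part of the spike-in level that varies within groups gave 129, and 2 of 100 random covariates gave as many (median 12, highest 169), so an extra covariate as such rarely does this. It held 41.8% of the within-group variance, where the largest axis held 42.7% and each of the axes would hold 25% if equal. The hybridization controls as covariate gave 4, and their within-group part gave 19. The fit without CTRL 3 gave 29. Within groups, however, the hybridization control mean ran with the spike-in mean (r = 0.82 over 6 arrays). The lower counts therefore cannot exclude hybridization strength. The count without CTRL 3 argues against that array as the whole source, though its fit has fewer arrays. A shared difference in RNA input, labelling or culture state among the arrays may underlie the rise in the count, and no biological explanation was tested.

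The 6 arrays can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. The real split gave 21 changed probe sets and the highest of the others 1, so 1 split reached 21. For 2-fold changes with an unadjusted p under 0.05 it gave 533 against 196, again reached by 1 split. For the gene lists past camera it gave 5, the highest other split gave 6, and 4 splits gave at least 5; the names had been selected on the real split.

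The hybridization controls averaged 11.23 ± 0.24 (SD, n = 3) in CTRL and 11.67 ± 0.42 in CBP (exact permutation p = 0.2). The 5th percentile of the positive controls was 7.93 ± 0.19 in CTRL and 7.36 ± 0.34 in CBP (exact permutation p = 0.1, the smallest that 3 against 3 can give).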
